A study of Mus musculus with 7 samples.

How the data were processed

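RNA was sequenced from interscapular brown adipose tissue, the heat-producing fat pad between the shoulder blades, of male C57BL/6J mice aged 10 weeks. Wild-type mice (WT) were compared with knockout mice (KO) lacking PGAM5, a phosphatase of mitochondria. Per the labels' protocols, frozen tissue was extracted with Isogen and libraries were made from poly(A)-selected RNA with a stranded kit. The labels list 3 WT and 4 KO samples as separate individuals. The count table used here has columns for 6 of these libraries, 3 WT and 3 KO, which were matched to samples by name. KO replicate 4 was not analysed here. The comparison is therefore 3 against 3, although 3 against 4 had been planned.

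The deposited values are raw counts per gene, whole numbers without normalization. Per the submitters' processing notes, HISAT2 2.1.0, featureCounts 1.6.2, DESeq2 and build mm10 were used. The DESeq2 version, the annotation release and the strand setting of the counting are not given in the sources used here. Reads from genes that overlap on opposite strands could therefore not be told apart. Reads can also be shared between near-identical copies. The table held 53715 gene identifiers, of which 53620 had a symbol in the reference table. Positions came from GENCODE release M 21, which is on the same build. Identical columns numbered 0, and no pair of libraries of a group differed by as little as sampling noise. Total counts ran from 18034204 to 33617762 per library. The limit that a count of 0 allows, 3 counts, lay between 0.0892 and 0.166 CPM. Such floors cover counting error only.

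Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 15123 genes holding 99.9% of all counts. Libraries were scaled with TMM factors. KO was compared with WT by the edgeR quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with genotype as the only term. The threshold was a Benjamini-Hochberg adjusted p of 0.05. CPM values are TMM-scaled, log2 CPM used a prior count of 2, and log2 fold changes are KO minus WT.

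The 36 gene lists, the tests and the rule for naming genes were fixed before the data were examined. Lists were tested on log2 CPM with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. These p-values were adjusted over the 36 lists. Members were also counted adjusted over the list alone. Members under the count filter or not found were not tested. Among called lists this left 12 of 23 T, NK and B cell, 17 of 26 skeletal muscle, 12 of 18 Schwann cell and 6 of 10 erythrocyte markers. A list score is the mean log2 CPM of the tested members in a library, compared by an exact two-sided permutation test. With 3 libraries against 3, that exact test cannot go below p = 0.1.

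Pgam5 was named first. Genes past the threshold with a mean CPM of at least 1 and no overlap between the groups followed, up to 10 in each direction, with predicted genes and pseudogenes named only near the top. Each list gave up to 4 members past the threshold or, with none, the 2 of highest mean CPM. Ucp1, Ppargc1a, Cidea, Dio2, Prdm16, Fgf21, Elovl3, Cox7a1, Pgam1 and Pgam2 were named whatever their values. Pxmp2, Rps13, Trim34a and genes named only in the closing section were chosen after their values were seen, as were added lists of hepatocyte and mast cell markers.

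The test was tested on simulated data, with counts of the 15123 genes drawn from the libraries' means and sizes in 5 draws. Each draw changed 100 genes 2-fold and 100 genes 4-fold. These genes were drawn among those with a mean CPM of at least 1. For KO against WT, edgeR recovered 91% of the 4-fold and 29.2% of the 2-fold changes, and 7.79% of its calls were false. It made 655 calls over the 5 draws, against 9 in the real comparison. With more calls a larger unadjusted p can pass, so the shares recovered do not carry over to the real comparison. DESeq2 recovered 93.4% and 45.2%, with 19.9% of calls false. Camera at an unadjusted p under 0.05 called a list of 25 genes shifted by 0.6 on the log2 scale in 5 of 5 draws. It called an unchanged list in 0 of 5, with the same counts at the preset and the estimated correlation. Simulated genes varied independently of each other. The draws therefore do not test lists whose members vary together, such as heat shock genes (estimated correlation 0.57).

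Alternatives were DESeq2 size factors, DESeq2 1.42.0, limma-voom, no filter and a stricter filter, a replicate block, a robust fit, other thresholds, and each library left out. After the data were seen, 4 more were added: leaving out both WT 2 and KO 3, voom with sample quality weights, leaving out mitochondrial genome genes, and DESeq2 on the filtered genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.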

Results

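Poly(A) RNA of interscapular brown fat was counted in 3 WT and 3 KO libraries. Total counts were 25001886, 18034204 and 33617762 in WT 1 to WT 3 and 21826942, 21240349 and 18952348 in KO 1 to KO 3. Genes of the mitochondrial genome took 32.5%, 43.0% and 30.3% of the WT counts and 34.1%, 28.2% and 19.7% of the KO counts. On the first principal component, which held 45.6% of the variance, WT 2 (-65.0) and KO 3 (66.8) stood apart from the other 4 libraries (-13.0 to 8.23).

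Pgam5, the gene removed in these mice, had 167, 122 and 186 counts in WT and 1, 3 and 11 counts in KO. Its level fell from 6.79 ± 1.33 CPM (SD, n = 3) to 0.237 ± 0.263 CPM (SD, n = 3), a log2 fold change of -4.84 (SE 0.59, edgeR adjusted p = 0.0243). The gene (ENSMUSG00000029500.16) lies on chromosome 5 from 110259130 to 110269913 (mm10). A gene on the opposite strand, Gm15788, with 166 counts in all, overlaps it. The call held without KO 3 (log2 -6.18) and ended when any other library was left out (log2 -4.97 to -4.35, edgeR adjusted p 0.0522 to 0.17). The related glycolytic genes Pgam1 and Pgam2 had log2 fold changes of 0.37 (SE 0.20) and 0.10 (SE 0.33) and did not pass. Of the 10 tested neighbours of Pgam5, 0 passed over all genes and 1, Pxmp2, was higher adjusted over the list alone (log2 1.53, SE 0.30). Pxmp2 encodes a peroxisomal membrane protein.

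The comparison asks how loss of PGAM5 alters gene expression in brown fat. Of 15123 genes tested, 3 were higher and 6 lower in KO. Fndc5, the gene of the irisin precursor, rose from 0.766 ± 0.562 CPM (SD, n = 3) to 12.4 ± 3.47 CPM (SD, n = 3), a log2 change of 3.91 (SE 0.46, edgeR adjusted p = 0.0208). Ucp2, an inner mitochondrial membrane carrier related to Ucp1, fell from 155 ± 18.5 CPM (SD, n = 3) to 44.4 ± 4.24 CPM (SD, n = 3), a log2 change of -1.80 (SE 0.17, edgeR adjusted p = 0.00804). Ccng2, which encodes cyclin G2, fell by 1.46 on the log2 scale (SE 0.16, edgeR adjusted p = 0.0174).

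The collagen receptor gene Ddr1 rose from 4.88 ± 0.706 to 17.5 ± 4.38 CPM (SD, n = 3 each) and the unconventional myosin gene Myo7a from 5.40 ± 0.309 to 15.7 ± 0.613 CPM. Their log2 fold changes were 1.84 (SE 0.24, edgeR adjusted p = 0.0392) and 1.54 (SE 0.19, edgeR adjusted p = 0.0243). Rnf150, a RING finger gene, fell from 26.7 ± 10.4 to 2.54 ± 0.613 CPM (SD, n = 3 each), log2 -3.39 (SE 0.33, edgeR adjusted p = 0.00804). Trim34b, a tripartite motif gene, had 81, 35 and 88 counts in WT and 1, 1 and 2 in KO, a log2 change of -5.37 (SE 0.54, edgeR adjusted p = 0.00804). The pseudogene Rps13-ps1 fell from 37.8 ± 12.8 to 2.99 ± 0.732 CPM (SD, n = 3 each), log2 -3.66 (SE 0.30, edgeR adjusted p = 0.00498). Reads can be shared with the copies Rps13 (log2 0.07, SE 0.26) and Trim34a (log2 0.11, SE 0.33), neither of which passed.

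The identifiers were ENSMUSG00000001334.9 for Fndc5, ENSMUSG00000033685.13 for Ucp2, ENSMUSG00000029385.14 for Ccng2, ENSMUSG00000003534.17 for Ddr1 and ENSMUSG00000030761.15 for Myo7a. Those of the called genes that fell most, Pgam5 left out, were ENSMUSG00000047747.10 for Rnf150, ENSMUSG00000090215.9 for Trim34b and ENSMUSG00000066362.5 for Rps13-ps1. Myo7a (98051060 to 98119524), Ucp2 (100493337 to 100502020) and Trim34b (104329471 to 104336909) lie on chromosome 7 (mm10). Rnf150 (82863356 to 83091268) and Rps13-ps1 (87047689 to 87048226) lie on chromosome 8. Myo7a, Ucp2, Trim34b, Rnf150, Rps13-ps1 and also Ucp1 lie in regions where genes of the smallest p lay close together, as given in the closing section. For genes there a strain haplotype that differs between the groups cannot be told apart from loss of PGAM5. Fndc5 lies on chromosome 4 from 129136999 to 129144593, Ddr1 on chromosome 17 from 35681567 to 35704621, and Ccng2 on chromosome 5 from 93267257 to 93276231. Dnajb13, on the strand opposite to Ucp2 and overlapping it, had 152 counts against 14090 for Ucp2.

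At an unadjusted p under 0.05 there were 952 higher and 830 lower genes, 1782 in all, against 756 in all by chance. The other 9 splits of the 6 libraries into 3 against 3 gave 229 to 1210 such genes. Groupings that mix the genotypes can thus also exceed 756. No overlap between the groups was seen for 19.5% of genes, against 10% by chance. DESeq2 called 85 higher and 82 lower genes, among them all 9 of the edgeR genes. Of the 9 genes, 0 were called without KO 2 (where 1443 genes had an unadjusted p under 0.05 in edgeR), 1 without KO 1, and 5 without WT 1, WT 3 or KO 3. Their directions held with each library left out. Without KO 2 the log2 fold changes were 4.03 for Fndc5, 1.54 for Myo7a, 1.89 for Ddr1 and -4.54 for Pgam5. The others were -5.17 for Trim34b, -3.59 for Rps13-ps1, -3.44 for Rnf150, -1.89 for Ucp2 and -1.44 for Ccng2. Ddr1 lost its call whichever library was left out (log2 1.63 to 1.99), with limma-voom and with the stricter filter, while Rps13-ps1 lost it only without KO 2. Without WT 2 there were 9 higher and 7 lower genes, and without both WT 2 and KO 3 14 and 12, among them all 9.

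**Figure D1:**
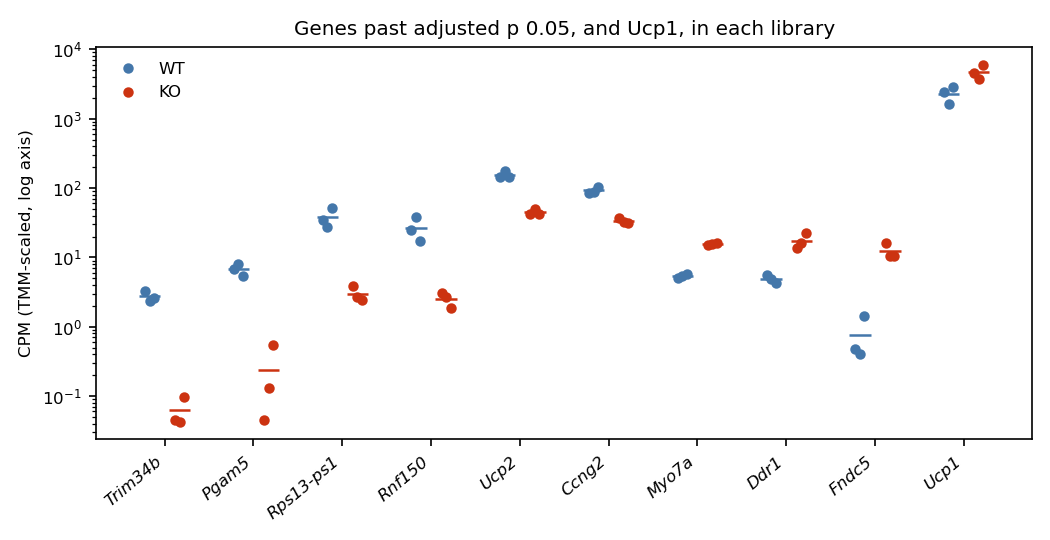
CPM (log axis) of the 9 genes past adjusted p 0.05 and of Ucp1 in each library; points are libraries (3 WT, 3 KO) and bars are group means. Ucp2 lay at 143 CPM or more in WT and at 49.3 CPM or less in KO.

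Ucp1, the uncoupling protein with which brown fat makes heat, was at 2297 ± 614 CPM (SD, n = 3) in WT and 4782 ± 1115 CPM (SD, n = 3) in KO. Every KO library lay above every WT library, but the log2 fold change of 1.06 (SE 0.28) did not pass (edgeR adjusted p = 0.310). DESeq2 gave an adjusted p of 0.00922, and the adjusted p ran from 0.00545 to 0.680 over the alternatives. The lowest came from edgeR with no filter. There the median total degrees of freedom, residual and prior together, were 111496, against 9.61 in the main fit. Without both WT 2 and KO 3 the log2 fold change was 0.67 (edgeR adjusted p = 0.342). Ucp1 (ENSMUSG00000031710.4) lies on chromosome 8 from 83290352 to 83298452 (mm10). Of the 13 tested genes within 0.5 Mb of Ucp1, 7 had an unadjusted p under 0.05, against 11.8% of all genes. Within 1 Mb there were 8 of 33.

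Elovl3, a fatty acid elongase of brown fat, was at 2.73 ± 0.805 CPM in WT and 22.1 ± 22.7 CPM in KO (SD, n = 3 each), with KO 3 at 48.2 CPM. Its log2 fold change of 2.99 (SE 0.65) did not pass (edgeR adjusted p = 0.305) and was 1.72 without KO 3. Elovl3 passed with DESeq2 (adjusted p = 0.0397), with DESeq2 on the filtered genes and with no filter, and its adjusted p ran from 2.61e-25 to 0.488 over the alternatives. The lowest came from edgeR with no filter, where the median total degrees of freedom were 111496 and the SE of Elovl3 was 0.27. That value rests little on the spread of Elovl3 between its own libraries. Other brown fat genes that did not pass were Ppargc1a (log2 -0.39, SE 0.32), Cidea (-0.07, SE 0.22), Dio2 (-0.44, SE 0.53), Prdm16 (0.46, SE 0.24) and Cox7a1 (-0.16, SE 0.30). Cidea and Cox7a1 turned positive without WT 2 (0.084 and 0.21). Values also moved for Ppargc1a without WT 1 (-0.028), Dio2 without WT 3 (-0.12) or KO 2 (-0.995) and Prdm16 without KO 3 (0.20). Fgf21 had 6 counts in all and was not tested. In the thermogenic list, 17 of 31 genes were positive, 0 passed over all genes and 1 was higher adjusted over the list alone. Its mean log2 fold change was 0.23 and its median 0.055, and the list was not called (camera adjusted p = 0.0869; adjusted p = 0.713 with an estimated correlation and 0.581 by fry; exact permutation p = 0.1). Without WT 2 it was called at the preset correlation, with a mean of 0.32 (camera adjusted p = 0.0132). The mean was 0.17 without WT 1 (camera adjusted p = 0.434) and 0.13 without KO 3 (0.0901).

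Heat shock genes, which encode chaperones, were called lower in KO. Of 16 members 15 were negative, 12 were lower adjusted over the list alone and 0 over all genes. The mean log2 fold change was -1.60 (camera adjusted p = 1.93e-07; adjusted p = 0.713 with an estimated correlation). Hsp90ab1 was at 1287 ± 327 CPM in WT and 717 ± 79.5 CPM in KO, and Hspa8 at 1169 ± 519 and 540 ± 257 CPM (SD, n = 3 each). List scores were 5.58, 5.70 and 7.40 in WT and 5.02, 5.13 and 4.96 in KO. Without WT 3 the mean was -0.60 (camera adjusted p = 3.87e-05).

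All 13 mitochondrially encoded mRNAs were negative, with a mean log2 fold change of -0.95 and a median of -0.60. The camera adjusted p was 0.00467 at the preset and 0.713 at an estimated correlation. Adjusted over the list alone 2 were lower, and over all genes 0. mt-Co1 was at 140482 ± 46675 CPM in WT and 90992 ± 35682 CPM in KO (SD, n = 3 each), and the log2 fold change of mt-Cytb was -0.41 (SE 0.32). The libraries of the groups overlapped (exact permutation p = 0.2), and the mean was -0.35 without WT 2, the library with the highest mitochondrial share. The call ended without both WT 2 and KO 3, the libraries with the highest and lowest share (mean -0.19, camera adjusted p = 0.102). Nuclear-encoded oxidative phosphorylation genes had a mean of -0.11 over 77 genes and were not called (camera adjusted p = 0.0864). That list was called without WT 1 (-0.16), WT 3 (-0.17) or KO 1 (-0.19), and with DESeq2. It turned positive without WT 2 (0.011) and without both WT 2 and KO 3 (0.041). With all 6 libraries its camera adjusted p was 0.876 with an estimated correlation.

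In lipid metabolism, fatty acid oxidation was called higher, with 24 of 30 genes positive and a mean log2 fold change of 0.23 (camera adjusted p = 0.0108; adjusted p = 0.713 with an estimated correlation). Its members of highest level, Hadhb (log2 0.00, SE 0.19) and Acaa2 (0.04, SE 0.19), stood near 0. The mean was 0.12 without KO 3, and the call ended without both WT 2 and KO 3 (mean 0.086, camera adjusted p = 0.110). Fatty acid and triglyceride synthesis was also called higher, with 24 of 26 positive and a mean of 0.63 (camera adjusted p = 0.000762; adjusted p = 0.713 with an estimated correlation). In both lists 0 members passed, over all genes or adjusted over the list alone. Fasn, fatty acid synthase, was at 8677, 305 and 3854 CPM in WT and at 2383, 4446 and 30944 CPM in KO. The call of the synthesis list ended without WT 2 (mean 0.39), without KO 3 (mean -0.028), without both (mean -0.27) and with sample quality weights (mean 0.16).

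Among cell type markers, those of T, NK and B cells were called higher, with 12 of 12 tested genes positive, of 23 listed. The mean log2 fold change was 0.90, and the camera adjusted p was 0.00278 at the preset and 0.713 at an estimated correlation. The call at the preset correlation held with each library left out. List scores were -0.57 ± 0.23 in WT and 0.23 ± 0.15 in KO (SD, n = 3 each, exact permutation p = 0.1). Adjusted over the list alone 2 members were higher, and over all genes 0. The immunoglobulin gene Ighm was at 3.86 ± 1.14 CPM in WT and 9.64 ± 4.60 CPM in KO (SD, n = 3 each). Interferon response genes were called higher, with 36 of 38 positive, 2 of them higher adjusted over the list alone and 0 over all genes. Their mean was 0.34 (camera adjusted p = 0.00103; adjusted p = 0.713 with an estimated correlation), and the call ended without KO 2 (mean 0.12).

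Stromal, vascular and nerve lists were called higher as well, each with an adjusted p = 0.713 with an estimated correlation and 0 members past the threshold over all genes. Extracellular matrix genes had a mean log2 fold change of 0.33 (29 of 35 positive, camera adjusted p = 0.000762), endothelial markers 0.29 (15 of 16, 0.0217) and pericyte and smooth muscle markers 0.32 (12 of 14, 0.0141). Fibroblast and preadipocyte markers had 0.24 (12 of 16, 0.0356) and Schwann cell and nerve markers 0.55 (11 of 12, 0.0141). Adjusted over the list alone, 1 matrix gene and 2 pericyte genes were higher, and 0 in the other 3 lists. Members of highest level went both ways, with Sparc at 0.05 (SE 0.18), Rgcc at -0.60 (SE 0.25), Rgs5 at -0.20 (SE 0.23), Gsn at 0.55 (SE 0.20) and S100b at -0.22 (SE 0.26). The endothelial call ended without WT 2 (0.18), KO 2 (0.26) or KO 3 (0.13), and the pericyte call without WT 1 (0.26) or KO 2 (0.32). The fibroblast call ended without WT 1 (0.16), KO 1 (0.24) or KO 2 (0.22), and the Schwann cell call without WT 2 (0.34), KO 1 (0.48) or KO 3 (0.35). Without KO 3 the matrix and pericyte means were 0.16 and 0.20, and without KO 1 the endothelial mean was 0.46. Without both WT 2 and KO 3 the matrix call ended (mean 0.079, camera adjusted p = 0.269), as did the endothelial (0.020) and Schwann cell (0.14) calls. The stricter filter ended the fibroblast and Schwann cell calls, and sample quality weights the endothelial and Schwann cell calls.

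Erythrocyte markers were called lower, with 6 of 6 negative, 1 lower adjusted over the list alone and 0 over all genes. Their mean log2 fold change was -0.46 (camera adjusted p = 0.0108; adjusted p = 0.713 with an estimated correlation), Hbb-bs stood at -0.40 (SE 0.23), and the call ended without KO 2 (mean -0.35). Skeletal muscle markers were called lower with 15 of 17 negative, 0 of them passing over all genes or adjusted over the list alone. Their mean was -0.57 (camera adjusted p = 0.0349; adjusted p = 0.772 with an estimated correlation). Muscle scores were 0.47, 0.93 and 1.80 in WT and -0.61, 1.74 and -0.37 in KO. The muscle call ended without WT 3 (mean 0.017), KO 1 (-0.22) or KO 3 (-0.28), and the mean was -2.15 without KO 2. It also ended with the stricter filter (mean -0.024, camera adjusted p = 0.889), DESeq2 (adjusted p = 0.0515), DESeq2 on the filtered genes (0.151), sample quality weights (0.200) and without both WT 2 and KO 3 (-0.30). Over the alternatives its adjusted p ran from 1.76e-06 to 0.889.

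Of the 36 lists, 13 were called by camera at the preset correlation, 0 at an estimated correlation and 0 by fry for a shift one way. For change in either direction fry called 4 lists: T, NK and B cells, neutrophils and mast cells, fibroblasts, and Pgam5 neighbours. Mean log2 fold changes of metabolic lists not called were -0.02 for beta-adrenergic response, 0.08 for TCA cycle, -0.02 for mitochondrial ribosome, 0.13 for lipolysis and lipid droplets, 0.24 for cholesterol synthesis, 0.11 for glucose uptake and glycolysis, 0.15 for branched-chain amino acid catabolism and 0.28 for creatine and calcium cycling. Stress and signalling lists not called stood at -0.07 for ATF4 targets (median 0.018), 0.04 for mitochondrial chaperones, -0.04 for mitochondrial dynamics, 0.04 for NRF2 targets, 0.13 for Wnt targets, -0.27 for NF-kappaB targets, 0.04 for the circadian clock, -0.01 for immediate early genes (median 0.088) and -0.01 for proliferation. White adipocytes stood at -0.03, macrophages at -0.01, neutrophils and mast cells at 0.49 and Pgam5 neighbours at 0.17 (median -0.053). In these lists 0 genes passed over all genes; adjusted over the list alone, 3 neutrophil and mast cell genes, 2 clock genes and 1 Pgam5 neighbour (Pxmp2) were higher, and 1 gene was lower in each of the neutrophil and mast cell, clock, beta-adrenergic, glycolysis and creatine lists.

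Some of these lists passed the threshold under an alternative, all at the preset correlation. Branched-chain amino acid catabolism was called without WT 2 (0.15), WT 3 (0.21) or KO 3 (0.13), with DESeq2 (adjusted p = 0.0177) and with no filter (0.0264), its adjusted p running from 0.0177 to 0.297 over the alternatives. Neutrophil and mast cell markers were called without WT 2 or KO 3 (0.68 each), with DESeq2 (adjusted p = 0.00948) and with DESeq2 on the filtered genes (0.0461), the adjusted p running from 0.00367 to 0.327. Cholesterol synthesis was called without WT 1 (0.40), KO 1 (0.38) or KO 2 (0.37), glycolysis without KO 1 (0.25) and NF-kappaB targets without WT 1 (-0.50). Each also turned the other way. Cholesterol synthesis stood at -0.11 and glycolysis at -0.14 without KO 3, and NF-kappaB targets at 0.18 without WT 2. Without both WT 2 and KO 3 cholesterol synthesis was called lower (-0.18, camera adjusted p = 0.0374). Mitochondrial ribosome genes were called higher without WT 2 (0.091).

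**Figure D2:**
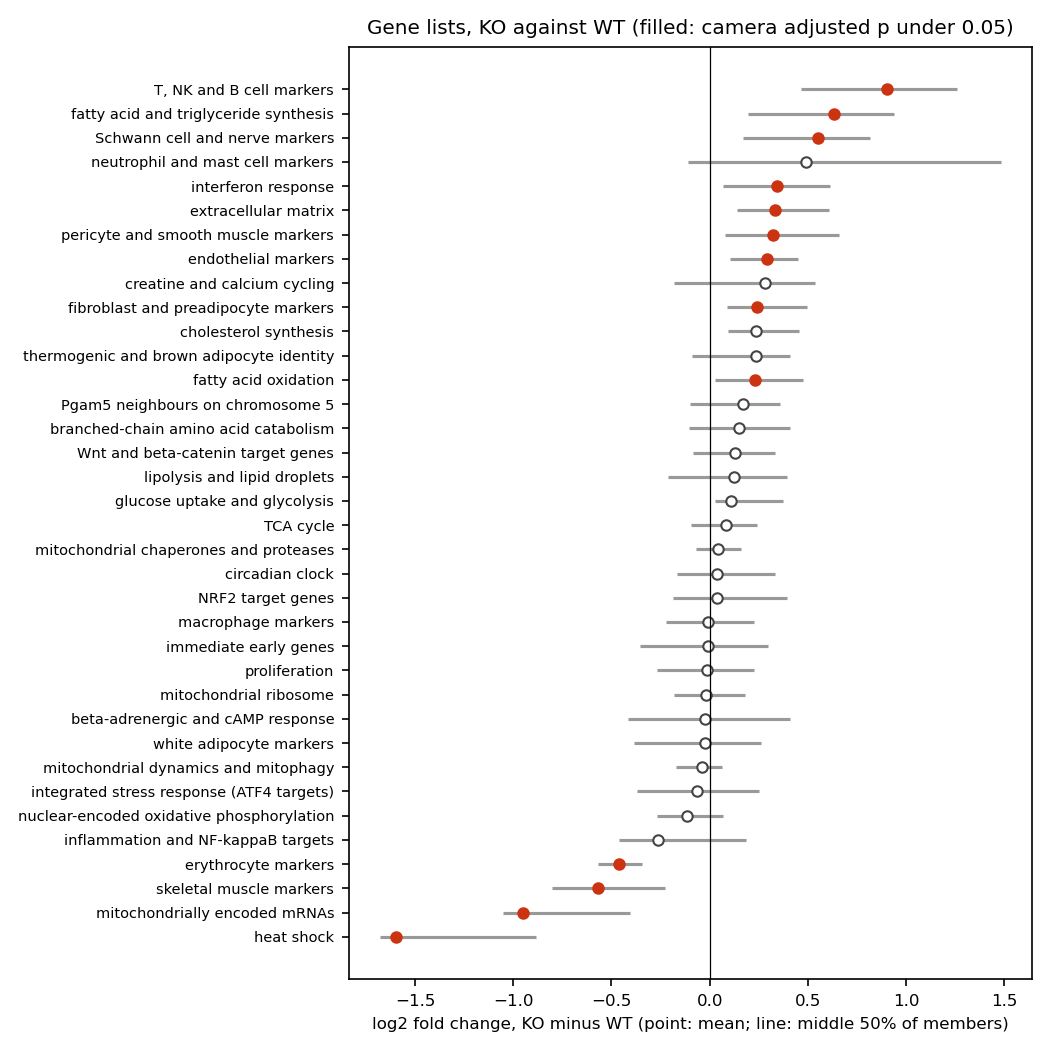
Mean log2 fold change (KO minus WT) of the tested members of each of the 36 lists (point) with the range of the middle 50% of members (line); filled points passed camera at the preset correlation. Heat shock (-1.60) lay farthest below 0 and T, NK and B cell markers (0.90) farthest above.

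**Figure D3:**
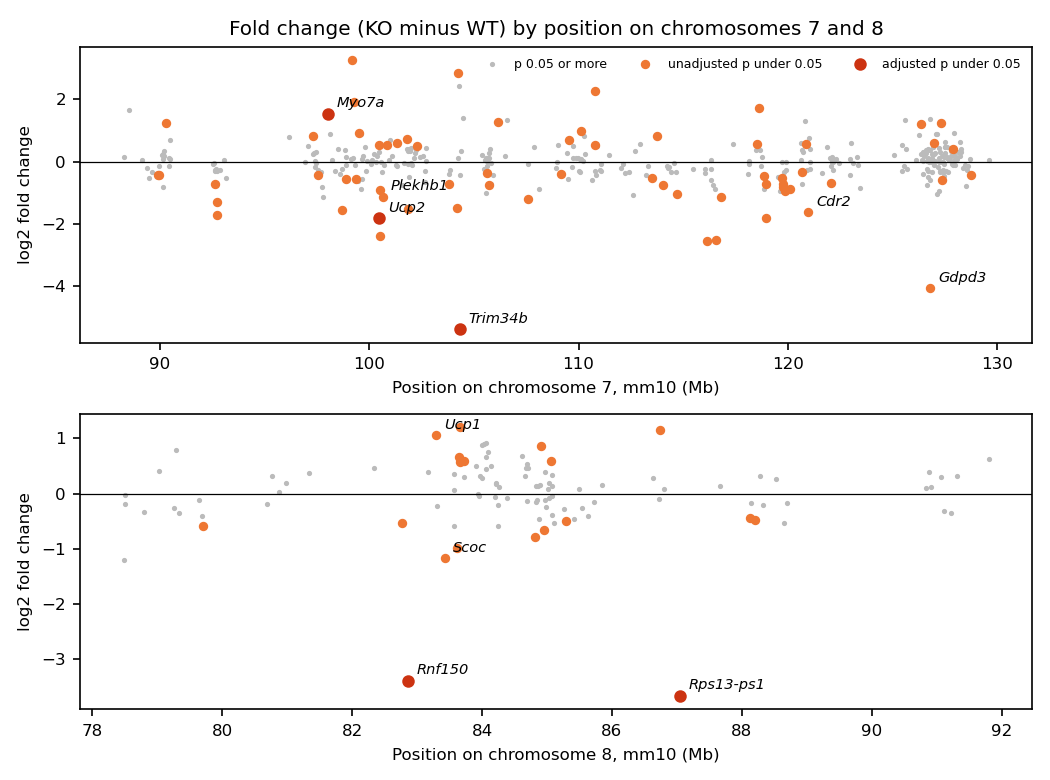
Log2 fold change (KO minus WT) of each tested gene by position (Mb, mm10) on parts of chromosomes 7 and 8 chosen after the values were seen, coloured by unadjusted and adjusted p. Rnf150 (-3.39), Ucp1 (1.06) and Rps13-ps1 (-3.66) lie within 10 Mb on chromosome 8, and Myo7a (1.54), Ucp2 (-1.80) and Trim34b (-5.37) within 10 Mb on chromosome 7.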

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

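Leaving out both WT 2 and KO 3, voom with sample quality weights, leaving out mitochondrial genome genes, and DESeq2 on the filtered genes were chosen after the data were seen. Of 993 alternative values, 790 kept their direction and side of the threshold, or lay within 1.5 times for counts. Of 863 values for single genes and lists other than Pgam5, Ucp1 and the thermogenic list, 66 lost their call and 29 gained one, 3 and 4 of them with a change of direction, and 70 changed direction in all. Any change of sign was counted, however small. The estimated correlation and fry entered these totals only through the thermogenic list and the count of called lists. The 13 list calls, which all ended under either of them, are therefore not among the 66. For the robust fit the list tests were taken over from the main fit, so those values were kept by construction. The alternatives for KO replicate 4 and for pseudocounts were not run. Except where a cause is given, the cause was not tested. Depth limits Pgam5 and Trim34b, which had 1 to 11 counts per KO library.

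Genes higher and lower in KO (3 and 6) numbered 85 and 82 with DESeq2, 101 and 86 with DESeq2 on the filtered genes, 330 and 333 with no filter on low counts, 14 and 12 without both WT 2 and KO 3, and 10 and 11 with sample quality weights. With no filter the median total degrees of freedom, residual and prior together, went from 9.61 to 111496. At adjusted p under 0.01 and under 0.1 there were 0 and 5 higher genes. With 1 library left out there were 0 to 9 higher and 0 to 8 lower genes, and 0 to 7 of the 9 were called. With replicate number as a block 1 gene was higher and 5 of the 9 were called; beside Pgam5, Ccng2 (-1.46, edgeR adjusted p = 0.0655), Myo7a (1.54, 0.0864) and Ddr1 (1.82, 0.109) lost their calls. Ddr1 also lost its call with limma-voom (1.83, adjusted p = 0.0659) and the stricter filter (1.84, edgeR adjusted p = 0.0520). Deviations of same-numbered libraries correlated at -0.114, 0.102 and 0.0909, and not every library correlated best with its own number. No pairing by number was seen, but so few correlations cannot exclude it.

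Pgam5 moved to -5.21 with limma-voom (adjusted p = 0.0531) and -4.95 with the replicate block (edgeR adjusted p = 0.0655), past the threshold in neither, and ran from -6.18 to -4.35 with 1 library left out. Ucp1 passed at 1.05 with both DESeq2 fits and at 1.06 with no filter. It was 0.67 without both WT 2 and KO 3 (edgeR adjusted p = 0.342) and ran from 0.86 to 1.24 with 1 library left out, past the threshold in none of these. The thermogenic list passed at 0.23 with DESeq2, 0.24 with no filter, 0.23 with the block, 0.21 without both WT 2 and KO 3 and 0.22 with sample quality weights, and ran from 0.13 to 0.32 with 1 library left out. These calls were at the preset correlation; with all 6 libraries in the main fit its adjusted p was 0.713 with an estimated correlation and 0.581 with fry. The count of 13 lists fell to 0 with an estimated correlation and to 0 with fry. Lists with no overlap of library scores numbered 10 with the stricter filter. DESeq2 called oxidative phosphorylation (-0.12), branched-chain amino acid catabolism (0.15) and neutrophil and mast cell markers (0.48).

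With limma-voom NRF2 targets moved to -0.0050, immediate early genes to 0.048 and white adipocytes to 0.00084, and with the stricter filter immediate early genes moved to 0.0052 and macrophages to 0.045. The stricter filter ended the calls of skeletal muscle (-0.024), fibroblast (0.21) and Schwann cell (0.46) markers, and the replicate block that of fibroblast markers (0.26). Without both WT 2 and KO 3, Cidea moved to 0.16, Dio2 to 0.072 and Cox7a1 to 0.37. Lists then moved to 0.041 for oxidative phosphorylation, -0.070 for TCA cycle, 0.12 for mitochondrial ribosome, -0.27 for fatty acid and triglyceride synthesis, -0.18 for cholesterol synthesis, -0.20 for glycolysis, -0.0015 for mitochondrial chaperones, 0.015 for mitochondrial dynamics, -0.034 for NRF2 targets, 0.33 for NF-kappaB targets, 0.12 for proliferation, 0.31 for white adipocytes and 0.27 for macrophages. Of these, mitochondrial ribosome (camera adjusted p = 0.00492) and macrophages (0.00817) were then called higher and cholesterol synthesis lower (0.0374). Branched-chain amino acid catabolism (0.13) and neutrophil and mast cell markers (0.87) were also called higher. Calls ended for fatty acid and triglyceride synthesis, mitochondrially encoded mRNAs (-0.19), fatty acid oxidation (0.086), extracellular matrix (0.079), endothelial (0.020), Schwann cell (0.14) and skeletal muscle (-0.30) lists. With sample quality weights Cidea moved to 0.021, Dio2 to 0.19 and Cox7a1 to 0.062. Lists moved to 0.038 for mitochondrial ribosome, -0.024 for cholesterol synthesis, -0.071 for glycolysis, -0.014 for NRF2 targets, 0.17 for NF-kappaB targets, 0.010 for immediate early genes, 0.098 for proliferation, 0.21 for white adipocytes and 0.18 for macrophages. Sample quality weights also ended the calls of fatty acid and triglyceride synthesis (0.16), endothelial (0.18), Schwann cell (0.19) and skeletal muscle (-0.55) markers, and branched-chain amino acid catabolism (0.15) and neutrophil and mast cell markers (0.68) were called.

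With 1 library left out, genes that crossed 0 ran from -0.19 to 0.084 for Cidea and -0.40 to 0.21 for Cox7a1. Other genes ran from -0.67 to -0.028 for Ppargc1a, -0.995 to -0.12 for Dio2, 0.20 to 0.66 for Prdm16, 1.72 to 3.41 for Elovl3, 0.19 to 0.48 for Pgam1 and 0.055 to 0.14 for Pgam2. Metabolic lists ran from -0.14 to 0.089 for beta-adrenergic response, -0.19 to 0.011 for oxidative phosphorylation, -0.029 to 0.14 for TCA cycle, -0.074 to 0.091 for mitochondrial ribosome, -0.028 to 0.92 for fatty acid and triglyceride synthesis, -0.11 to 0.40 for cholesterol synthesis, -0.14 to 0.25 for glycolysis and -0.032 to 0.47 for creatine and calcium cycling. Stress and signalling lists ran from -0.19 to 0.076 for ATF4 targets, -0.012 to 0.074 for mitochondrial chaperones, -0.081 to 0.0071 for mitochondrial dynamics, -0.040 to 0.069 for NRF2 targets, -0.50 to 0.18 for NF-kappaB targets, -0.049 to 0.25 for the circadian clock, -0.35 to 0.27 for immediate early genes and -0.15 to 0.099 for proliferation. Cell type lists ran from -0.17 to 0.15 for white adipocytes, -2.15 to 0.017 for skeletal muscle and -0.14 to 0.19 for macrophages.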

Other observations

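The camera and fry tests of the heat shock list were planned, and so were leaving out WT 3 and the test of the immediate early list, which were applied to the heat shock pattern only later. The other tests in this part were chosen after the results they bear on were seen. Mast cell genes, a list added then, were positive in 6 of 6 tested members (mean log2 fold change 1.31), of which 4 were higher adjusted over the list alone and 0 over all genes. List scores were 0.726 ± 0.173 in WT and 1.90 ± 0.497 in KO (SD, n = 3 each, exact permutation p = 0.1). The list shares genes with the neutrophil and mast cell list. Trim12a, the neighbour of Trim34b, was at 0.0808, 7.74 and 0 CPM in WT 1, WT 2 and WT 3 and at 11.5, 15.5 and 10.7 CPM in KO. The real split of the libraries gave 9 genes past the edgeR threshold and was the 1 split of 10 with as many; the highest of the others gave 0. With 10 splits a share under 0.05 cannot be reached.

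Genes with the smallest p lay close together on chromosomes 7 and 8. Of the 50 smallest, Pgam5 left out, 10 lay in 35 Mb of chromosome 7 from 92 Mb. A further 3 lay in 6 Mb of chromosome 8 from 82 Mb. From the share of tested genes there, 0.992 and 0.251 would be expected, but the regions were drawn around the pattern. The 50 held 34 pairs within 10 Mb, against a 95th percentile of 19 in 10000 shuffles of positions (permutation p = 0.0004). The number 50 was picked after looking at 4 sizes; the 20, 100 and 200 smallest held 7, 100 and 274 pairs, against 95th percentiles of 4, 62 and 223. The tables argue against reads shared between neighbouring copies, since 31 pairs lay over 1 Mb apart (95th percentile 16). For the 50 they argue against neighbours that vary together whatever the grouping, since the other 9 splits gave at most 17 pairs. For the 200 another split gave 234, above the 95th percentile of 223. These splits mix the genotypes, so they cannot show neighbours that change together with loss of PGAM5. Strain haplotypes that differ between the mice stay open as a candidate explanation: of the other genes in these regions, which were drawn around the pattern, 16.9% on chromosome 7 had p under 0.05, above the 95th percentile of windows (16.2%), but the 17.8% on chromosome 8 lay under its 19.2%. Loss of PGAM5 stays open too. Within 1 Mb of Ucp1, 24.2% of genes had p under 0.05. There a haplotype and loss of PGAM5 cannot be told apart, because both would part the same 3 libraries from 3. On chromosome 7 Gdpd3 was at 1.94, 26.7 and 31.1 CPM in WT 1 to WT 3 and at 1.07 to 1.36 CPM in KO. Trim5 was at 0.0404, 1.33 and 0.0589 CPM in WT 1 to WT 3 and at 2.49 to 3.55 CPM in KO. These differences among WT libraries, like that of Trim12a, do not follow genotype. The genes were picked after their values were seen, so they decide nothing for the others.

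Heat shock genes were called lower in KO by camera at the preset correlation only, with adjusted p = 0.713 with an estimated correlation, adjusted p = 0.479 by fry and 0 members past the threshold over all genes. At that preset correlation the tables argue against WT 3 alone as the cause, since without it the list was still called lower, at a mean of -0.60 (camera adjusted p = 3.87e-05), although most of the mean of -1.60 went with that library. A handling stress that also raises immediate early genes cannot be told apart from other causes, because that list, at a mean of -0.0093 (camera adjusted p = 0.780), had members on both sides of 0. Loss of PGAM5 stays open and was not tested.

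Hepatocyte transcripts, a list of 25 genes added after the data were seen, were lowest in KO 3 for 25 of 25 genes; 0 of the 25 are in another list, and how many of them brown fat expresses was not tested. Alb was at 237, 412, 242, 206 and 263 CPM in WT 1, WT 2, WT 3, KO 1 and KO 2 and at 10.9 CPM in KO 3. Loss of PGAM5 as the cause of the near absence is argued against by KO 1 and KO 2, whose list scores of 3.28 and 3.65 stood far above the -0.26 of KO 3. KO 2 lay above WT 1 (3.41) and WT 3 (3.51), but KO 1 lay under all 3 WT libraries, so a smaller lowering stays open. Liver RNA from 1 source in the other 5 libraries is a candidate explanation: there the counts of the 25 genes lay nearer to 1 ratio than those of other genes, with a chi-square per degree of freedom of 2.16, against a median of 17.5 and a lowest value of 7.43 in 1000 sets of genes matched on count. Counts simulated from 1 source with sampling noise alone gave 1.02, so the ratio was not fully constant. The matched sets held genes of any kind, not markers of 1 cell type, and no other cell type list was compared. The value therefore cannot part 1 source from several. Whether such RNA came with the tissue or during library preparation was not tested.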
